A study of Mus musculus with 17 samples.

How the data were processed

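RNA of periprostatic fat from 17 male C57BL/6J mice was measured, each on its own Affymetrix Mouse Gene 2.0 ST array, with 6 mice on a low-fat diet (LFD), 6 on a high-fat diet (HFD) and 5 on the high-fat diet with restricted intake (HFD_CR). Per the labels' protocols the mice were separate animals and RNA had an integrity number above 7. The hour of harvest and the feeding state at harvest are not given in the sources used here. The deposited values are log2 expression per probe set, and per the submitters' processing notes RMA, limma and R 3.5.0 were used, with no version given for the first pair and no role or order for any. RMA corrects background, normalizes between arrays and summarises probes. The deposited values ran from 4.55 to 14.4 log2 units, and the range and array medians were checked to be those of a log2 scale.

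The table held 33793 probe sets. The annotation gave exactly 1 gene symbol for 23521 of them, several for 1814 and none for 8458. Of several probe sets of a gene the one with the highest mean over all arrays was used, which left 22180 genes. Probe sets with no or several symbols were left out of the gene comparisons and counted on their own. No filter on dim probe sets and no rescaling were applied. Where the lower group of a largest change lay below every array's median, the difference was also taken with the array's median in place of each lower signal, which was chosen after the data were seen. Genome positions are not reported, since the files name no build. Cyp19a1 was not analysed here.

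A mean per group was fitted to each gene over all 17 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 14 residual and 3.625 prior degrees of freedom), and 3 contrasts were taken: HFD minus LFD, HFD_CR minus HFD, and HFD_CR minus LFD. A gene was said to rise or fall when its Benjamini-Hochberg adjusted p, over all genes in the comparison, was under 0.05. Errors of gene differences are standard errors from this fit. Exact permutation tests of list means covered both directions and every split of the mice into groups of the same sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

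Before the data were examined, 41 gene lists were fixed with 813 genes, of which 739 were measured. They cover macrophages, lipid-associated macrophages, the lysosome, cytokines and chemokines, complement, MHC class II presentation, the interferon response, T cells, B and plasma cells, NK cells, mast cells and granulocytes. For metabolism they cover de novo lipogenesis, cholesterol biosynthesis, triglyceride synthesis and lipid uptake, lipolysis and the lipid droplet, adipocyte identity, adipokines, thermogenic adipocytes, fatty acid oxidation, oxidative phosphorylation, the TCA cycle and branched-chain amino acid catabolism. Further lists cover the extracellular matrix, adipose progenitors, insulin signalling, hypoxia, endothelium, oxidative stress, the unfolded protein response, the cell cycle, the circadian clock, immediate early genes, and steroid receptors and metabolism. Lists for other tissues cover prostate and accessory gland epithelium, urothelium, mesothelium, smooth muscle, skeletal muscle, Schwann cells and nerve, and erythroid cells. Each list was tested with camera on the same fit (preset correlation between genes of 0.01, both directions, Benjamini-Hochberg over the lists), and again with the correlation estimated from the data and with fry. The count of members that rose or fell was also taken with p adjusted over the list alone. After the data were seen, 5 marker lists were added: male germ cell, fasting-responsive genes of adipose tissue, imprinted gene network, and the Bmal1 arm and the Dbp and Per arm of the clock.

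The rule for named genes was set before the data were examined. It takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those that passed, up to 4 passing members of each list with the largest difference (or the 2 with the smallest p where none passed), and 12 measured genes fixed in advance, from Lep to Ucp1. The largest changes left out predicted genes, clone names, small RNAs, immune receptor segments and odorant, vomeronasal and taste receptors.

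Alternatives set beforehand were leaving out each array in turn, the mouse number as a block, only genes above the median level, probe sets averaged per gene, every probe set tested on its own, quantile normalization applied again, centring on array medians, only the arrays of the groups compared, eBayes with trend and robust, array weights, at least a 1.5-fold change, adjusted p under 0.01, covariates for gland epithelium and for B and T cells, both other list tests, and splits of the HFD arrays into sets of 3. Chosen after seeing the data were leaving out the 4 arrays with other tissue, leaving out LFD mice 3 and 6, and a skeletal muscle covariate.

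The procedure was tested on simulated data with the spread of the real arrays, in which 200 genes were changed per comparison. For changes of 0.5 log2 units 94.03%, 80.6% and 89.55% were recovered in HFD minus LFD, HFD_CR minus HFD and HFD_CR minus LFD, with 12, 7 and 9 false calls. Of 20 unchanged lists 0 were called in each comparison, and of 20 lists shifted by 0.5 residual SDs 15, 9 and 15 were called. The simulated genes were independent of each other, whereas members of the real lists were correlated (0.651 estimated for the cell cycle list). The simulation therefore does not show how often the list test makes false calls on the real lists.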

Results

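Gene expression was measured in periprostatic fat, the adipose depot around the prostate, of 17 male C57BL/6J mice, with 1 Affymetrix Mouse Gene 2.0 ST array per mouse. The low-fat group (LFD, n = 6) ate a diet with 10 kcal% fat, and the high-fat group (HFD, n = 6) ate 60 kcal% fat without restriction. The restricted group (HFD_CR, n = 5) ate the high-fat diet for 12 weeks and then, for 7 weeks, 70% of the amount eaten by the HFD group. Diets started at 6 weeks of age and tissue was taken at 25 weeks. Values are log2 array signals, and the number of arrays limits the precision. The median signal of an array lay between 7.03 and 7.15. Across genes, the median correlation of arrays was 0.993 within groups and 0.985 between groups. Each difference between groups is a log2 difference ± SE unless stated otherwise, and each adjusted p for a gene is from limma with Benjamini-Hochberg adjustment over 22180 genes. For a gene list, the mean difference is the mean over its members, with the SE between mice, and its adjusted p is from camera over 41 lists. Camera called 21, 19 and 15 lists in HFD against LFD, HFD_CR against HFD and HFD_CR against LFD, and with a correlation between genes estimated from the data it called 0 in each (smallest adjusted p 0.0916, 0.108 and 0.158), whereas fry called 22, 21 and 15. Apart from these tests, 6, 2 and 3 of the called lists lost their call under at least 1 of 30 or 29 alternatives, and 5 of 20, 3 of 22 and 11 of 26 lists with no call passed under at least 1.

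Transcripts of neighbouring tissues stood high on some arrays. The mean of the skeletal muscle list lay above the median array by 2.97 in LFD mouse 2, 1.88 in LFD mouse 3, 1.95 in HFD_CR mouse 2, 0.94 in HFD mouse 6 and 0.75 in LFD mouse 5. The prostate and accessory gland epithelium list lay above the median array by 2.05 in LFD mouse 3 and 1.09 in HFD mouse 3. The urothelium list had a mean of 0.91 in LFD mouse 3 and at most 0.08 in the other mice, relative to the mean of all arrays. Ucp1, the uncoupling protein of brown and beige adipocytes, measured 12.6 in LFD mouse 3 and 12.1 in LFD mouse 6, against 6.17 to 10.3 in the other mice. Without the 4 arrays whose muscle or gland list lay more than 1 above the median array, a setting chosen after the data were seen, 3287 genes were higher and 2269 lower in HFD than in LFD, 1569 higher and 2278 lower in HFD_CR than in HFD, and 1030 higher and 655 lower in HFD_CR than in LFD. This setting kept HFD mouse 6. It also kept HFD_CR mouse 1, whose mean over the male germ cell list was 9.48, against at most 7.72 in the other mice.

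**Figure D1:**
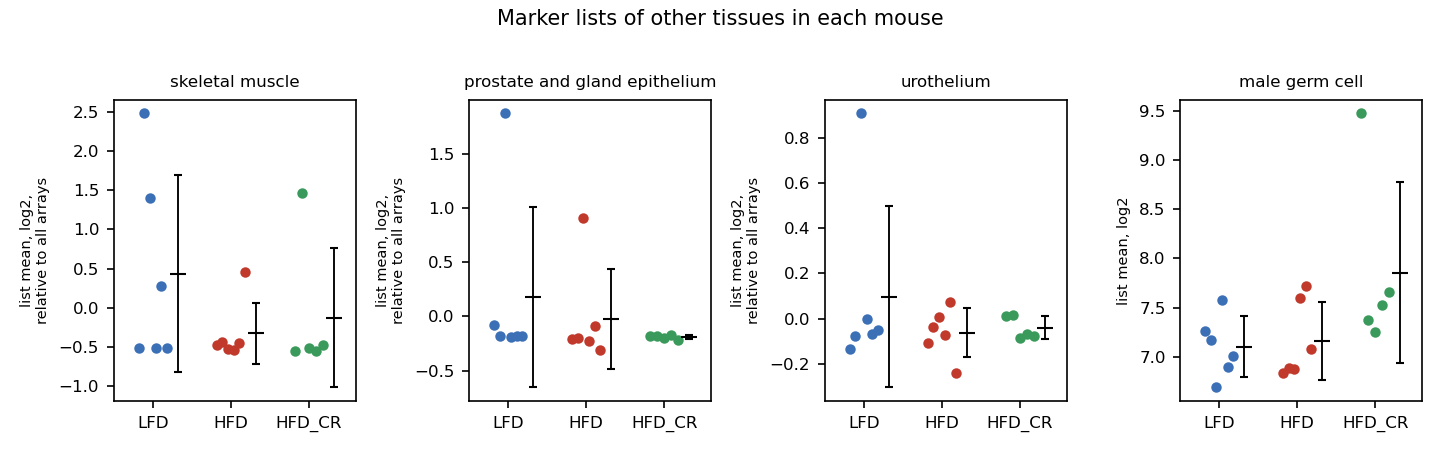
Mean of 4 marker lists of other tissues in each mouse, by group, with the group mean ± SD as the black mark beside the points. The first 3 panels are log2 relative to the mean of all arrays and the last is the mean log2 signal. LFD mouse 2, LFD mouse 3 and HFD_CR mouse 2 stand high for skeletal muscle, LFD mouse 3 and HFD mouse 3 for gland epithelium, LFD mouse 3 for urothelium, and HFD_CR mouse 1 for male germ cells at 9.48.

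The comparison of HFD with LFD asked how a high-fat diet changes this fat depot. Macrophage genes rose, led by Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, which measured 12.0 ± 0.24 in HFD (SD, n = 6) and 6.67 ± 0.49 in LFD (SD, n = 6). The LFD signal lay below the median of every array and was not shown to be above background, so the size of the difference is uncertain: it was 5.33 as measured and 4.88 with array medians in place of the lower LFD signals. Genes of cell division and of the extracellular matrix rose with them. Genes for making fatty acids and for breaking down branched-chain amino acids fell. The largest fall of a named gene was that of the acute phase protein gene Orm3, which fell by 3.31 ± 0.20. In all, 3663 genes were higher and 2502 lower in HFD, so that 59.4% of the changed genes were higher. The share higher was 47.9% (3076 higher, 3347 lower) when each array was centred on its median. At least a 2-fold difference was seen for 293 genes that rose and 75 that fell.

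After Atp6v0d2 (probe set 17423577), the genes with the largest rises in measured signal were Tm4sf19 (4.25 ± 0.26), the integrin gene Itgad (3.92 ± 0.30), the macrophage elastase gene Mmp12 (3.74 ± 0.30), Gpnmb (3.67 ± 0.28), the orphan receptor gene Gpr50 (3.60 ± 0.20), the interleukin 7 receptor gene Il7r (3.20 ± 0.28) and Cdkl4 (3.11 ± 0.23). After Orm3, the largest falls were those of Serpina3b (-2.99 ± 0.35), the paraoxonase gene Pon1 (-2.98 ± 0.26), Sly (-2.65 ± 0.38), the cytochrome P450 gene Cyp2f2 (-2.59 ± 0.24), the albumin gene Alb (-2.36 ± 0.20), the fatty acid elongase gene Elovl6 (-2.26 ± 0.22) and the claudin gene Cldn22 (-2.04 ± 0.20). Cyp2f2 fell by 1.65 when its probe sets were averaged. Adjusted p values of these 16 genes ran from 5.52e-09 (Orm3) to 2.9e-05 (Sly), and the values of the HFD mice and of the LFD mice overlapped for none of them, which their choice for large differences favours. Over all 22180 genes, 14.3% had no overlap between these groups, where chance gives 0.216%. For Atp6v0d2, Itgad, Cdkl4, Serpina3b, Pon1, Sly and Cldn22 the mean of the lower group lay below 7.03, where the signal was not shown to be above background, so their measured sizes and ranks are uncertain. With array medians in place of lower signals the differences were 3.35 for Itgad, 2.21 for Cdkl4, -2.47 for Serpina3b, -2.60 for Pon1, -1.37 for Sly and -1.88 for Cldn22. Sly has many near-identical copies, and Orm3, Serpina3b and Cyp2f2 have close relatives, so the gene behind their signal is uncertain.

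In the macrophage list, 14 of 16 genes rose and none fell, with 14 rising and 1 falling adjusted over the list alone. Examples are Itgax (2.99 ± 0.23), Cd68 (1.92 ± 0.15) and Adgre1 (1.31 ± 0.14). The mean difference was 1.15 ± 0.11 (adjusted p = 1.16e-11, and adjusted p = 0.0916 with an estimated correlation). In the list of lipid-associated and crown-like structure macrophages, which surround dying adipocytes, 16 of 19 rose and 1 fell, the same counts as adjusted over the list alone. Trem2 rose by 3.07 ± 0.21, and Acp5, named after its value was seen as the member that fell, had a difference of -0.34 ± 0.04. The mean was 1.91 ± 0.09 (adjusted p = 4.33e-15, and adjusted p = 0.0916 with an estimated correlation). Among lysosomal genes 21 of 23 rose and 1 fell, likewise adjusted over the list alone, including the cathepsin genes Ctsk (2.70 ± 0.17) and Ctss (1.92 ± 0.17), with a mean of 0.70 ± 0.05 (adjusted p = 7e-16, and adjusted p = 0.0916 with an estimated correlation).

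Of 29 inflammatory cytokine and chemokine genes, 16 rose and 2 fell, with 17 and 2 adjusted over the list alone. The monocyte chemoattractant gene Ccl2 rose by 2.57 ± 0.20, Ccl7 by 2.26 ± 0.23 and Tnf by 0.80 ± 0.10, whereas Il6 had a difference of 0.02 ± 0.05 (adjusted p = 0.778). The list mean was 0.58 ± 0.06 (adjusted p = 5.81e-07, and adjusted p = 0.0942 with an estimated correlation). Of 16 complement genes 10 rose and 2 fell, 11 and 2 adjusted over the list alone, led by the receptor genes C3ar1 (1.69 ± 0.13) and C5ar1 (1.57 ± 0.11). The complement list had adjusted p = 4.96e-05, and adjusted p = 0.129 with an estimated correlation. Of 14 genes for antigen presentation on MHC class II, 8 rose, 10 with 1 fall adjusted over the list alone, among them H2-DMb1 (0.81 ± 0.12). The mean of that list was 0.21 ± 0.09 (adjusted p = 0.0134, and adjusted p = 0.599 with an estimated correlation). Its call ended without LFD mouse 6 (0.15, adjusted p = 0.0517), among genes above the median level (0.14, adjusted p = 0.259), without the 4 arrays with other tissue (0.15, adjusted p = 0.0616) and without LFD mice 3 and 6 (0.10, adjusted p = 0.109).

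All 25 cell cycle genes rose, also when adjusted over the list alone, with a mean of 0.97 ± 0.10 (adjusted p = 3.63e-22, and adjusted p = 0.0916 with an estimated correlation). The mitotic kinase gene Cdk1 rose by 1.71 ± 0.08 and the proliferation marker Mki67 by 1.38 ± 0.12. Of 32 genes of the extracellular matrix and fibrosis 28 rose, 31 adjusted over the list alone, and none fell, with Timp1, an inhibitor of matrix metalloproteinases, at 2.87 ± 0.21 and the proteoglycan gene Lum at 1.99 ± 0.12. The list mean was 0.73 ± 0.07 (adjusted p = 6.67e-18, and adjusted p = 0.0916 with an estimated correlation). Of 20 immediate early genes 11 rose and 1 fell, 13 and 1 adjusted over the list alone, led by Atf3 (2.49 ± 0.17) and Fos (1.73 ± 0.11). The immediate early list had adjusted p = 6.34e-06, and adjusted p = 0.0916 with an estimated correlation. Of 22 genes of the unfolded protein response 12 rose and 2 fell, also adjusted over the list alone. The chaperone gene Hspa5 rose by 0.38 ± 0.07, and Asns, which makes asparagine, fell by 0.72 ± 0.07. That list had adjusted p = 0.005 and adjusted p = 0.437 with an estimated correlation, and among genes above the median level its call ended (0.16, adjusted p = 0.0865).

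**Figure D2:**
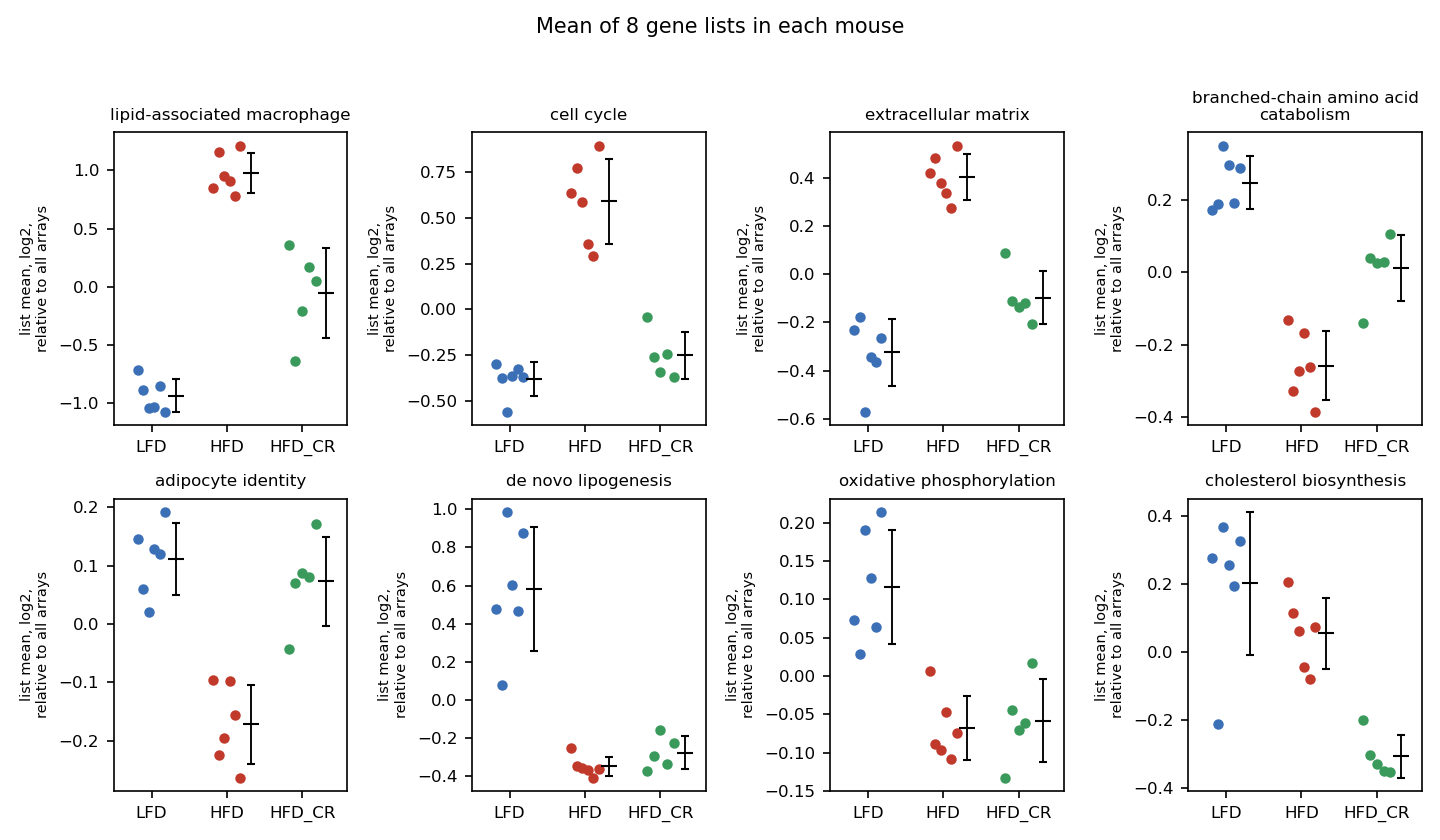
Mean of 8 gene lists in each mouse, in log2 relative to the mean of all arrays, by group, with the group mean ± SD as the black mark beside the points. De novo lipogenesis means lie at 0.08 or above in every LFD mouse and at -0.16 or below in every HFD and HFD_CR mouse.

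Several lists of lipid and energy metabolism were called lower, whereas cholesterol biosynthesis and thermogenic adipocyte genes had no call. In de novo lipogenesis, the making of fatty acids from other nutrients, 18 of 20 genes fell and none rose, 19 adjusted over the list alone, and the mean was -0.93 ± 0.13 (adjusted p = 7.84e-16, and adjusted p = 0.0942 with an estimated correlation). Acaca, which makes malonyl-CoA, fell by 1.82 ± 0.14, Thrsp by 1.65 ± 0.11 and the fatty acid synthase gene Fasn by 0.85 ± 0.07. In branched-chain amino acid catabolism 20 of 21 fell, 21 adjusted over the list alone, with Ivd at -0.89 ± 0.08 and Bckdha at -0.82 ± 0.09 and a mean of -0.51 ± 0.05 (adjusted p = 5.13e-18, and adjusted p = 0.0916 with an estimated correlation). Of 20 TCA cycle genes 14 fell, 15 adjusted over the list alone, for example Pdhb (-0.69 ± 0.07) of pyruvate dehydrogenase. The TCA cycle list had adjusted p = 3.34e-09, and adjusted p = 0.22 with an estimated correlation. Of 46 genes of oxidative phosphorylation 26 fell and 1 rose, 28 and 1 adjusted over the list alone, for example Ndufa10 (-0.48 ± 0.07). The oxidative phosphorylation list had adjusted p = 5.33e-10, and adjusted p = 0.22 with an estimated correlation. LFD mice 3 and 6, which stood high for thermogenic adipocyte genes (1.06 and 0.83), also had the highest means of lipogenesis (0.99 and 0.87), the TCA cycle (0.34 and 0.30) and oxidative phosphorylation (0.19 and 0.21). Without these mice the differences were -0.76 for lipogenesis (adjusted p = 4.9e-14), -0.47 for branched-chain amino acid catabolism (adjusted p = 4.71e-16), -0.24 for the TCA cycle (adjusted p = 2.85e-07) and -0.14 for oxidative phosphorylation (adjusted p = 3.72e-07), so these mice carried part of each difference.

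Of 20 adipocyte identity genes 14 fell and 1 rose, the same counts as adjusted over the list alone, and the mean was -0.28 ± 0.04 (adjusted p = 1.01e-06, and adjusted p = 0.188 with an estimated correlation). The insulin-responsive glucose transporter gene Slc2a4 fell by 1.13 ± 0.09 and the adiponectin gene Adipoq by 0.28 ± 0.06, whereas the leptin gene Lep, near the upper end of the signal range, rose by 0.44 ± 0.08. Of 18 genes of triglyceride synthesis and lipid uptake 9 fell and 1 rose, 10 and 1 adjusted over the list alone, led by Mogat1 (-1.33 ± 0.10). The triglyceride synthesis and lipid uptake list had adjusted p = 8.73e-05, and adjusted p = 0.123 with an estimated correlation. Of 18 genes of lipolysis and the lipid droplet 8 fell and 1 rose, 9 and 2 adjusted over the list alone. The phosphodiesterase gene Pde3b fell by 0.60 ± 0.06 and the droplet coat gene Plin2 rose by 0.71 ± 0.08. The lipolysis and lipid droplet list had adjusted p = 0.0127, and adjusted p = 0.374 with an estimated correlation. The mean falls of the TCA cycle (-0.30), triglyceride synthesis (-0.26), oxidative phosphorylation (-0.18) and lipolysis (-0.17) lists were close to or smaller than that of adipocyte identity. A lower share of adipocyte RNA was not tested for them. In HFD_CR minus LFD the means were -0.28 for the TCA cycle and -0.17 for oxidative phosphorylation, against -0.04 for adipocyte identity. Scd1, also near the upper end of the range, fell by 0.16 ± 0.03, a call that ended with quantile normalization applied again (-0.04, adjusted p = 0.438).

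Calls were also made for 4 further lists, each of which lost its call under some alternative. Of 17 circadian clock genes 6 fell, also adjusted over the list alone, for example Hlf (-0.43 ± 0.09). The circadian clock list had adjusted p = 0.0134, and adjusted p = 0.291 with an estimated correlation, and the call ended without LFD mice 3 and 6 (-0.13, adjusted p = 0.0667). Of 25 genes of fatty acid oxidation 9 fell and 1 rose, also adjusted over the list alone. Eci1 fell by 0.46 ± 0.07, and Cpt1a, which lets fatty acids into mitochondria, rose by 0.74 ± 0.05, with a list mean of -0.10 ± 0.05 (adjusted p = 0.0301, and adjusted p = 0.646 with an estimated correlation). That call ended without HFD mouse 2 (-0.0865, adjusted p = 0.0545), HFD mouse 5 (-0.0949, adjusted p = 0.0536), LFD mouse 3 (-0.0732, adjusted p = 0.111) or LFD mouse 6 (-0.0697, adjusted p = 0.0794), without LFD mice 3 and 6 together (-0.0312, adjusted p = 0.394), without the 4 arrays with other tissue (-0.0817, adjusted p = 0.107), with array weights (-0.0814, adjusted p = 0.0992), with a gland epithelium covariate (-0.0874, adjusted p = 0.0613) and when arrays were centred on their medians (-0.13, adjusted p = 0.0518). In the skeletal muscle list 1 of 18 genes fell, Myl1 (-0.71 ± 0.14), also adjusted over the list alone, and the mean was -0.77 ± 0.54 (adjusted p = 0.0134, and adjusted p = 0.685 with an estimated correlation). It was -0.36 without LFD mouse 2 (adjusted p = 0.141), -0.57 without LFD mouse 3 (adjusted p = 0.0655), -0.45 with array weights (adjusted p = 0.139), and 0.03 without the 4 arrays with other tissue (adjusted p = 0.831). In the mesothelium list 1 of 12 genes fell and none adjusted over the list alone, with a mean of -0.27 ± 0.15 (adjusted p = 0.0457, and adjusted p = 0.685 with an estimated correlation). Leaving out LFD mouse 2, 3 or 6 or HFD mouse 2, 3, 5 or 6 ended that call, with means from -0.27 to -0.19 and adjusted p from 0.0583 to 0.135, and without LFD mice 3 and 6 together the mean was -0.11 (adjusted p = 0.387). It was -0.12 without the 4 arrays with other tissue (adjusted p = 0.343), and in all 14 of 30 alternatives ended the call (-0.30 to -0.11, adjusted p of 0.0583 to 0.387).

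The other 20 lists had no call between HFD and LFD, and the counts in brackets are those adjusted over the list alone. Of 21 genes of adipokines and secreted factors 9 rose and 7 fell (10 and 7, adjusted p = 0.881), with Mest at 1.61 ± 0.21 and the angiotensinogen gene Agt at -1.40 ± 0.09. Of 21 oxidative stress genes 8 rose and 5 fell (8 and 6, adjusted p = 0.343), with the heme oxygenase gene Hmox1 at 1.57 ± 0.10 and Gsta4 at -1.55 ± 0.13. Of 24 insulin signalling genes 5 rose and 8 fell (5 and 8, adjusted p = 0.0867), a list that passed in 3 of 30 alternatives, among them without HFD mouse 4 (-0.16 to -0.15, adjusted p of 0.0234 to 0.0482). Of 18 genes of adipose progenitors and fibroblasts 7 rose and 2 fell (7 and 2, adjusted p = 0.0685), a list that passed in 4 of 30 alternatives, among them without HFD_CR mouse 5 (0.13 to 0.19, adjusted p of 0.0342 to 0.0476), and of 20 hypoxia genes 7 rose and 2 fell (8 and 5, adjusted p = 0.44). Among 18 genes of steroid hormone receptors and metabolism 1 rose and 3 fell (1 and 3, adjusted p = 0.421), including the estrogen receptor gene Esr1 (-0.44 ± 0.08). Of 18 endothelial genes 1 fell (0, adjusted p = 0.281), of 10 urothelium genes 1 fell (0, adjusted p = 0.707), and of 12 Schwann cell and nerve genes 1 rose and 2 fell (1 and 2, adjusted p = 0.845). None of the 18 gland epithelium genes passed (0, adjusted p = 0.351), and only 2 of the 10 erythroid genes were measured, neither passing (0, adjusted p = 0.905).

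In the lists of other immune cells, 2 of 18 T cell genes rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.707), among them Il7r. Of 11 NK cell genes 2 fell (0 adjusted over the list alone, adjusted p = 0.347), none of 11 mast cell genes passed (0, adjusted p = 0.845), and of 15 granulocyte genes 3 rose and 2 fell (3 and 2, adjusted p = 0.473), with Mmp9 at -1.33 ± 0.12 and S100a8 at 0.65 ± 0.11. Of 20 interferon response genes 2 rose and 2 fell (2 and 2, adjusted p = 0.268), with Gbp3 at -0.58 ± 0.09. Of 16 B cell and plasma cell genes 1 rose and 3 fell (1 and 3, adjusted p = 0.0636), with Blnk at 1.33 ± 0.12. The B cell list passed without HFD mouse 3 (-0.40, adjusted p = 0.00531), HFD mouse 4 (-0.33, adjusted p = 0.0401) or LFD mouse 6 (-0.43, adjusted p = 0.00273), without the 4 arrays with other tissue (-0.39, adjusted p = 0.0109) and without LFD mice 3 and 6 (-0.48, adjusted p = 0.00163), and in all in 8 of 29 alternatives (adjusted p of up to 0.0474). Of 13 smooth muscle genes 3 rose and 1 fell (3 and 1, adjusted p = 0.963), with Synpo2 at 1.16 ± 0.17. The mean and median differed in sign for the T cell list (0.0816 and -0.057) and for the smooth muscle list (0.0173 and -0.0837), and camera placed both downwards. Ucp1 had a difference of -1.90 ± 0.80 (adjusted p = 0.0895), which passed without LFD mouse 4 (-2.53, adjusted p = 0.0113).

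Some members moved against their list and were named after their values were seen. The chemokine gene Cxcl9 fell by 0.84 ± 0.07 and Il18 by 0.33 ± 0.09 while other cytokine genes rose, and C2 and C6 fell by 0.76 ± 0.09 and 0.50 ± 0.11 while other complement genes rose. Vldlr, a lipoprotein receptor gene, rose by 0.44 ± 0.07 and Ndufb3 by 0.20 ± 0.06, whereas Xbp1 fell by 0.21 ± 0.05 and Nr4a2 by 0.36 ± 0.07.

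**Figure D3:**
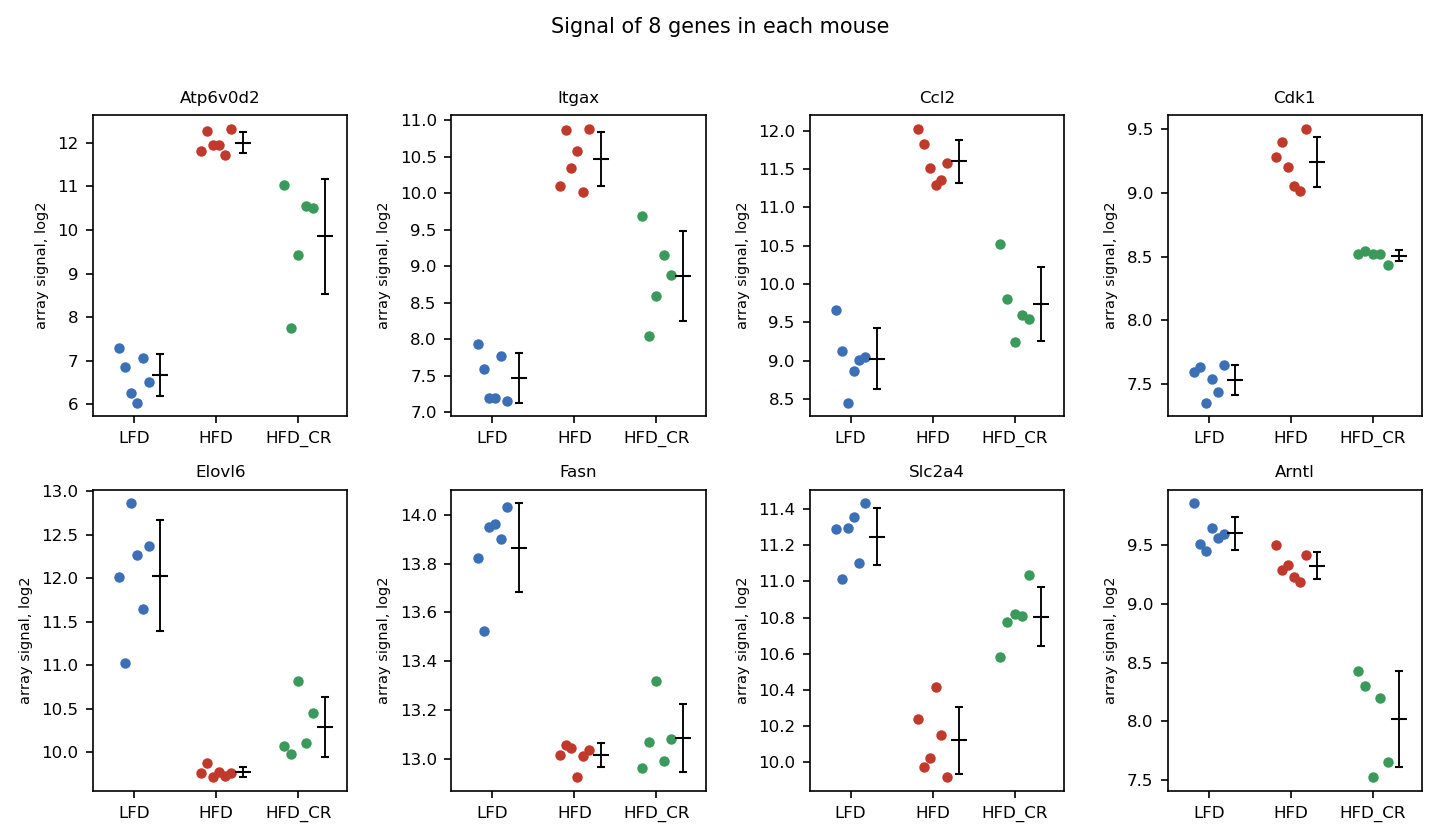
Log2 array signal of 8 genes in each mouse, by group, with the group mean ± SD as the black mark beside the points. Atp6v0d2 averages 6.67 in LFD, 12.0 in HFD and 9.85 in HFD_CR, and Fasn averages 13.9, 13.0 and 13.1.

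The comparison of HFD_CR with HFD asked what calorie restriction changes while the high-fat diet goes on. Macrophage, cell cycle, matrix and inflammatory genes fell. Timp1 fell by 2.27 ± 0.22, Itgad fell by 2.23 ± 0.31 and Ccl2 fell by 1.86 ± 0.21, each with n = 5 and n = 6 mice. Genes of adipocyte identity and of branched-chain amino acid catabolism rose, and clock genes moved in both directions, with the clock output gene Dbp 2.75-fold higher in HFD_CR. In all, 1705 genes were higher and 2508 lower in HFD_CR, and at least a 2-fold difference was seen for 30 that rose and 128 that fell.

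The largest rises in measured signal were those of Sly (2.53 ± 0.39), Orm3 (1.91 ± 0.21), Fam13a (1.60 ± 0.22), Dbp (1.46 ± 0.15), Fcamr (1.28 ± 0.16), Astx5 (1.26 ± 0.32), Timp4 (1.20 ± 0.12) and Alb (1.19 ± 0.21), of which Sly and Astx5 are multi-copy genes with uncertain signal. The HFD mean of Sly, 5.79, lay below the median of every array and was not shown to be above background, and with array medians in its place the difference was 1.25, below that of Orm3. Besides Timp1, Itgad and Ccl2, the largest falls were those of Tm4sf19 (-2.20 ± 0.27), the retinol dehydrogenase family gene Dhrs9 (-2.18 ± 0.24), Atp6v0d2 (-2.15 ± 0.42), Rnf128 (-1.89 ± 0.39) and the membrane protease gene Adam8 (-1.87 ± 0.23). Adjusted p values ran from 6.47e-06 (Timp1 and Timp4) to 0.00871 (Astx5). Among these 16, chosen for large differences, the values of the groups overlapped for Astx5 and Alb. Over all genes 13.7% had no overlap between these groups, where chance gives 0.433%.

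In the macrophage list 14 of 16 genes fell and 1 rose, also adjusted over the list alone, with a mean of -0.82 ± 0.10 (adjusted p = 8.8e-11, and adjusted p = 0.108 with an estimated correlation). Itgax fell by 1.59 ± 0.24, the Fc receptor gene Fcgr4 by 1.56 ± 0.16 and Cd68 by 0.99 ± 0.15, while Mertk, a receptor for the uptake of dying cells that was named after its value was seen, rose by 0.39 ± 0.07. Of 19 lipid-associated macrophage genes 16 fell, also adjusted over the list alone, for example Slc37a2 (-1.84 ± 0.19), with a mean of -1.03 ± 0.19 (adjusted p = 1.52e-13, and adjusted p = 0.108 with an estimated correlation). Of 23 lysosomal genes 21 fell, also adjusted over the list alone, with Ctsk at -1.67 ± 0.17 (list adjusted p = 1.7e-16, and adjusted p = 0.108 with an estimated correlation). Of 29 cytokine and chemokine genes 15 fell and 1 rose, 16 and 2 adjusted over the list alone, among them Ccl7 (-1.68 ± 0.24) and Tnf (-0.71 ± 0.10). The cytokine and chemokine list had adjusted p = 2.3e-07, and adjusted p = 0.108 with an estimated correlation. Complement genes fell in 8 of 16 cases and rose in 1, 9 and 2 adjusted over the list alone, with C3ar1 at -1.11 ± 0.13. The complement list had adjusted p = 0.000287, and adjusted p = 0.192 with an estimated correlation. Of 14 MHC class II presentation genes 9 fell, also adjusted over the list alone, with H2-DMb1 at -0.58 ± 0.12. The MHC class II list had adjusted p = 0.000187, and adjusted p = 0.299 with an estimated correlation.

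All 25 cell cycle genes fell, also adjusted over the list alone, by a mean difference of -0.84 ± 0.11 (adjusted p = 3.49e-26, and adjusted p = 0.108 with an estimated correlation), with Mki67 at -1.33 ± 0.12 and the topoisomerase gene Top2a at -1.30 ± 0.14. Of 32 matrix and fibrosis genes 23 fell, 27 adjusted over the list alone, and the collagen gene Col6a3 had a difference of -0.94 ± 0.10, with a list mean of -0.50 ± 0.06 (adjusted p = 1.31e-14, and adjusted p = 0.111 with an estimated correlation). Of 20 immediate early genes 12 fell and 1 rose, 13 and 1 adjusted over the list alone, with Atf3 at -1.62 ± 0.18. The immediate early list had adjusted p = 7.65e-06, and adjusted p = 0.108 with an estimated correlation. Of 22 unfolded protein response genes 12 fell and 1 rose, 16 and 2 adjusted over the list alone, with Hspa5 at -0.57 ± 0.07. The unfolded protein response list had adjusted p = 6.08e-05, and adjusted p = 0.248 with an estimated correlation. Of 19 cholesterol biosynthesis genes 13 fell and 1 rose, 16 and 1 adjusted over the list alone, with Cyp51 at -0.95 ± 0.19 and Dhcr7 at -0.67 ± 0.10, and the list mean was -0.36 ± 0.05 (adjusted p = 3.23e-07, and adjusted p = 0.258 with an estimated correlation).

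Several lists of adipocyte function were called higher in HFD_CR than in HFD. Of 20 adipocyte identity genes 14 rose and 2 fell, 16 and 2 adjusted over the list alone, with Klf15 at 0.82 ± 0.13, Slc2a4 at 0.69 ± 0.10 and Adipoq at 0.32 ± 0.06, and a list mean of 0.25 ± 0.04 (adjusted p = 8.67e-08, and adjusted p = 0.152 with an estimated correlation). Of 21 genes of branched-chain amino acid catabolism 15 rose, 17 with 1 fall adjusted over the list alone, with Ivd at 0.59 ± 0.08 and a mean of 0.27 ± 0.06 (adjusted p = 2.17e-10, and adjusted p = 0.192 with an estimated correlation). Of 18 genes of triglyceride synthesis and lipid uptake 7 rose and 2 fell, 8 and 3 adjusted over the list alone, with Pck1, which feeds glycerol synthesis, at 1.09 ± 0.13. The triglyceride synthesis and lipid uptake list had adjusted p = 0.00499, and adjusted p = 0.258 with an estimated correlation. Of 18 genes of lipolysis and the lipid droplet 8 rose and 2 fell, 10 and 2 adjusted over the list alone, with Plin4 at 0.35 ± 0.06 and Plin2 at -0.66 ± 0.09. The lipolysis and lipid droplet list had adjusted p = 0.00659, and adjusted p = 0.299 with an estimated correlation. Of 24 insulin signalling genes 8 rose and 4 fell, 12 and 4 adjusted over the list alone, with Irs2 at 0.52 ± 0.11. The insulin signalling list had adjusted p = 0.022, and adjusted p = 0.34 with an estimated correlation, and without HFD mouse 5 this call ended (0.14, adjusted p = 0.0608). Of 18 genes of steroid hormone receptors and metabolism 7 rose and 2 fell, 8 and 2 adjusted over the list alone, with Esr1 at 0.54 ± 0.08 and Hsd11b1, which activates glucocorticoids, at 0.50 ± 0.09. That list had adjusted p = 0.0204 and adjusted p = 0.108 with an estimated correlation, and its call ended among genes above the median level (0.21, adjusted p = 0.0525).

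Of 17 circadian clock genes 11 rose and 4 fell, also adjusted over the list alone, and the list mean was 0.36 ± 0.07 (adjusted p = 0.000147, and adjusted p = 0.111 with an estimated correlation). Dbp, Per3 (1.15 ± 0.14) and Nr1d1 (1.10 ± 0.14) rose, and Arntl, which encodes the clock activator BMAL1, fell by 1.31 ± 0.13. Of 12 mesothelium genes 6 rose, 9 adjusted over the list alone, with Rspo1 at 0.70 ± 0.13 and a mean of 0.47 ± 0.17 (adjusted p = 0.000147, and adjusted p = 0.34 with an estimated correlation). No call between HFD_CR and HFD was made for de novo lipogenesis, where 2 of 20 genes rose and 2 fell (mean 0.07 ± 0.04, adjusted p = 0.372) and Fasn had a difference of 0.07 ± 0.08 (adjusted p = 0.638). Oxidative phosphorylation, with 4 of 46 genes higher and 4 lower (adjusted p = 0.414), and the TCA cycle, with 3 of 20 higher and 2 lower (adjusted p = 0.374), had no call either. Lep had a difference of -0.14 ± 0.08 (adjusted p = 0.282). Named after their values were seen as members against their list, Cxcl9 rose by 0.47 ± 0.07, C2 by 0.62 ± 0.09 and the squalene synthase gene Fdft1 by 0.51 ± 0.12, and Socs3 and Ptpn1, which restrain insulin signalling, fell by 0.40 ± 0.09 and 0.32 ± 0.07. In fatty acid oxidation (6 of 25 higher and 1 lower, adjusted p = 0.364) and hypoxia (5 of 20 higher and 4 lower, adjusted p = 0.934) the mean (0.0426 and 0.0432) and the median (-0.0074 and -0.0345) differed in sign. The endothelial list (adjusted p = 0.0585) passed without HFD_CR mouse 1 or 3 or HFD mouse 3, 4, 5 or 6, with means of 0.0987 to 0.12 and adjusted p of 0.0179 to 0.0447, and in all in 10 of 30 alternatives (adjusted p of 0.0163 to 0.0497). HFD mouse 1 was low for endothelial genes (-0.52 from the mean of the other HFD mice), which enlarges that difference. The interferon response list passed in 3 of 30 alternatives (-0.20 to -0.18, adjusted p of 0.0247 to 0.0457), among them without HFD mouse 5, and the thermogenic adipocyte list in 1, with only the arrays of these groups fitted (-0.21, adjusted p = 0.0437).

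Of the 3663 genes higher in HFD than in LFD, 2085 (56.9%) were lower in HFD_CR than in HFD, and of the 2502 lower genes 1058 (42.3%) were higher, together 3143 genes. Timp1, Ccl2, Itgad and Tm4sf19 are examples of the first kind and Orm3 and Alb of the second. Genes of both kinds are called changed back below. No tissue was taken when restriction began, so a reversal cannot be told from a change that arose later in the HFD group alone. Both comparisons share the HFD arrays, so opposite changes also arise by chance. In 50 simulations with no effect and the same shared arrays the highest number was 0, but few genes pass without effects, so this does not show how many opposite calls shared arrays add to real ones. Independent lists of these sizes would share 607 genes. With the 6 HFD arrays split into sets of 3, one for each comparison, the 20 splits gave 1565 to 2147 genes (median 1931), against at most 368 for independent lists. The correlation of differences across genes, which are not independent replicates, was -0.765 against -0.477 in the simulations. The covariance, to which shared arrays add the same amount with or without effects, was -0.0555 against -0.00432.

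**Figure D4:**
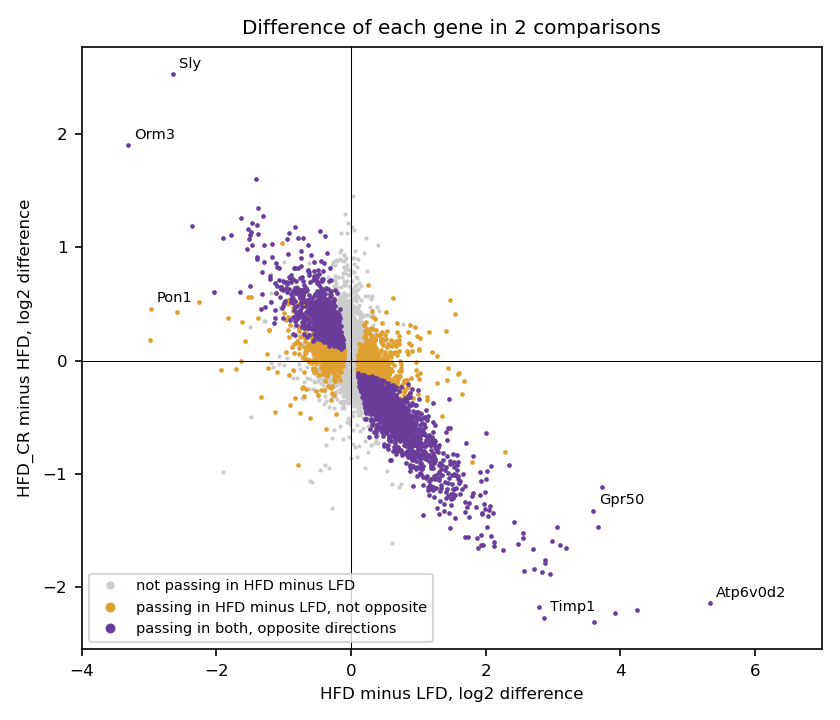
Log2 difference of each gene between HFD and LFD (horizontal) and between HFD_CR and HFD (vertical), 1 point per gene. Purple points mark the 3143 genes that passed in both comparisons with opposite signs, orange points other genes that passed between HFD and LFD, and grey points the rest.

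The comparison of HFD_CR with LFD asked which differences from mice on the low-fat diet are left after restriction. Genes of lipid-associated macrophages were higher, with Mmp12 at 2.62 ± 0.31 and Gpnmb at 2.19 ± 0.29 (n = 5 and n = 6 mice). Genes of fatty acid synthesis were lower, with Elovl6 at -1.74 ± 0.23 and Fasn at -0.78 ± 0.08. The cholesterol biosynthesis list was lower as well. It had no call between HFD and LFD (mean -0.15) and was called lower in HFD_CR than in HFD (mean -0.36). The oxidative phosphorylation and TCA cycle lists were called lower too, and the clock genes Arntl (-1.58 ± 0.13) and Dbp (1.48 ± 0.15) differed in opposite directions. Arntl and Dbp differed in the same directions between HFD_CR and HFD. In all, 1287 genes were higher and 728 lower in HFD_CR. Of the genes higher in HFD, 852 (23.3%) were also higher in HFD_CR than in LFD, and of those lower in HFD, 507 (20.3%) were also lower, together 1359 genes. Both comparisons share the LFD arrays, so such agreement also arises by chance. Independent lists of these sizes would share 295 genes, and in the 50 simulations with no effect, where few genes pass, the highest number was 0. With the 6 LFD arrays split into sets of 3, one for each comparison, the 20 splits gave 449 to 1142 genes (median 696), against 84.3 to 228 for independent lists. The covariance of differences across genes was 0.0399 against 0.00437 in the simulations.

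The largest rises in measured signal were those of Atp6v0d2 (3.19 ± 0.42, against a dim LFD signal), Mmp12, Gpr50 (2.27 ± 0.21), Gpnmb, Tm4sf19 (2.05 ± 0.27), the imprinted gene Peg3 (2.01 ± 0.21), the secreted Wnt inhibitor gene Sfrp5 (1.95 ± 0.48) and Itgad (1.69 ± 0.31). The largest falls were those of Ucp1 (-2.88 ± 0.84), Serpina3b (-2.81 ± 0.36), Pon1 (-2.52 ± 0.27), Cyp2f2 (-2.15 ± 0.26), Asb12 (-2.01 ± 0.15), Cidea (-1.78 ± 0.41), Elovl6 and Angptl8 (-1.71 ± 0.25). Adjusted p values ran from 2.69e-06 (Asb12) to 0.0371 (Ucp1), and among these 16, chosen for large differences, the values of the groups overlapped for Ucp1. Over all genes 6.67% had no overlap between these groups, where chance gives 0.433%. For Atp6v0d2, Itgad, Ucp1, Serpina3b and Asb12 the mean of the lower group lay below 7.03, so their measured sizes and ranks are uncertain. With array medians in place of lower signals the differences were 2.74, 1.11, -2.51, -2.33 and -1.70. The Ucp1 call ended without any single one of HFD_CR mice 1, 2, 3 and 4 and LFD mice 1, 3 and 6, with differences of at least 2.33 in size and adjusted p of up to 0.0923. Without LFD mice 3 and 6, the mice with the highest Ucp1, Cidea fell by 1.08 and Sfrp5 rose by 1.17, and Sfrp5 had adjusted p = 0.0611 when only the arrays of these groups were fitted. LFD mice 3 and 6 together also enlarge the fall of Ucp1, so its size depends on them. With probe sets averaged, Cyp2f2 fell by 1.36 and Asb12 by 1.09.

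In de novo lipogenesis 17 of 20 genes fell, 19 adjusted over the list alone, with Acly, which makes cytosolic acetyl-CoA, at -1.66 ± 0.13 and Acaca at -1.44 ± 0.15, and the mean was -0.86 ± 0.14 (adjusted p = 1.35e-26, and adjusted p = 0.158 with an estimated correlation). Of 19 cholesterol biosynthesis genes 14 fell, 16 adjusted over the list alone, with Cyp51 at -1.28 ± 0.19 and Sqle at -0.97 ± 0.12 and a mean of -0.51 ± 0.09 (adjusted p = 6.84e-17, and adjusted p = 0.211 with an estimated correlation). That list had no call between HFD and LFD, where 5 of 19 fell and 2 rose (adjusted p = 0.0743), and it passed in 5 of 30 alternatives: without LFD mouse 2 (-0.23, adjusted p = 0.000385), HFD mouse 1 (-0.18, adjusted p = 0.0293) or the 4 arrays with other tissue (-0.21, adjusted p = 0.00163), with a skeletal muscle covariate (-0.21, adjusted p = 0.0102) and with quantile normalization again (-0.18, adjusted p = 0.0229). Of 46 genes of oxidative phosphorylation 20 fell, 35 adjusted over the list alone, with Ndufa10 at -0.38 ± 0.07. The oxidative phosphorylation list had adjusted p = 1.7e-16, and adjusted p = 0.211 with an estimated correlation. Of 20 TCA cycle genes 15 fell, 17 with 1 rise adjusted over the list alone, with Pdhb at -0.68 ± 0.08. The TCA cycle list had adjusted p = 3.84e-14, and adjusted p = 0.211 with an estimated correlation. Of 21 genes of branched-chain amino acid catabolism 13 fell, 20 adjusted over the list alone, with Mccc1 at -0.37 ± 0.08. The branched-chain amino acid catabolism list had adjusted p = 3.65e-13, and adjusted p = 0.211 with an estimated correlation. Without LFD mice 3 and 6 the differences were -0.68 for lipogenesis (adjusted p = 3.56e-23), -0.13 for oxidative phosphorylation (adjusted p = 1.76e-10), -0.21 for the TCA cycle (adjusted p = 1.53e-10) and -0.20 for branched-chain amino acid catabolism (adjusted p = 1.13e-09). The circadian clock list had no call against LFD, with 8 of 17 genes higher and 4 lower (adjusted p = 0.054), and it passed without any one of HFD_CR mice 1 and 2, HFD mouse 4 and LFD mice 3, 5 and 6 (0.19 to 0.24, adjusted p of 0.00518 to 0.0498), and in all in 11 of 30 alternatives. Fatty acid oxidation had no call, with 3 of 25 genes lower and 1 higher, 5 and 1 adjusted over the list alone (mean -0.0557, adjusted p = 0.0749), and it passed without HFD_CR mouse 5 (-0.089, adjusted p = 0.00561), LFD mouse 1 (-0.0707, adjusted p = 0.0292) or LFD mouse 5 (-0.0749, adjusted p = 0.0216) and with a B and T cell covariate (-0.11, adjusted p = 0.0014). Without LFD mice 3 and 6 its mean was 0.0114 (adjusted p = 0.918). Adipocyte identity had no call, with 3 of 20 genes higher and 2 lower (adjusted p = 0.296), and Adipoq had a difference of 0.05 ± 0.06 (adjusted p = 0.727).

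In the lipid-associated macrophage list 14 of 19 genes rose and 1 fell, 14 and 2 adjusted over the list alone, with Trem2 at 1.59 ± 0.22 and a mean of 0.88 ± 0.18 (adjusted p = 7.44e-10, and adjusted p = 0.211 with an estimated correlation). Of 16 macrophage genes 6 rose, also adjusted over the list alone, with Itgax at 1.40 ± 0.24 and Cd68 at 0.93 ± 0.15. The macrophage list had adjusted p = 0.000263, and adjusted p = 0.483 with an estimated correlation. Of 23 lysosomal genes 7 rose and 1 fell, 9 and 1 adjusted over the list alone, with Ctsk at 1.03 ± 0.17. The lysosome list had adjusted p = 0.000119, and adjusted p = 0.483 with an estimated correlation. Of 32 matrix and fibrosis genes 11 rose, 13 with 2 falls adjusted over the list alone, with the thrombospondin gene Thbs2 at 1.36 ± 0.13. The matrix and fibrosis list had adjusted p = 2.91e-05, and adjusted p = 0.483 with an estimated correlation. Tnf differed by 0.09 ± 0.10 (adjusted p = 0.679) and Adgre1 by 0.32 ± 0.14 (adjusted p = 0.198). The call of Ccl2 (0.72 ± 0.21, adjusted p = 0.0406) ended without any one of HFD_CR mice 1, 2, 4 and 5, HFD mice 3 and 6 and LFD mice 3, 4, 5 and 6 (down to 0.52, adjusted p of up to 0.113). That of Lep (0.29 ± 0.08, adjusted p = 0.0359) ended without any one of HFD_CR mice 1, 2, 4 and 5 and LFD mice 4 and 6 (down to 0.22, adjusted p of up to 0.0981).

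In the thermogenic adipocyte list 6 of 19 genes fell and 1 rose, 9 and 1 adjusted over the list alone, and the mean was -0.62 ± 0.21 (adjusted p = 1.84e-05, and adjusted p = 0.211 with an estimated correlation). Without LFD mice 3 and 6, whose list means were 1.06 and 0.83, it was -0.30 (adjusted p = 0.000536). Prdm16, the member that rose, had a difference of 0.29 ± 0.09 (adjusted p = 0.0495) and was named after its value was seen. Between HFD and LFD this list had 4 genes lower and 1 higher (adjusted p = 0.0636), and it passed without LFD mouse 2, 4 or 5 and with a B and T cell covariate (-0.51 to -0.47, adjusted p of 0.027 to 0.0287). LFD mice 3 and 6 enlarge the difference in that comparison as well. Of 20 interferon response genes 5 fell and 2 rose, 10 and 2 adjusted over the list alone, with Rtp4 at -0.60 ± 0.15. The interferon response list had adjusted p = 0.000132, and adjusted p = 0.483 with an estimated correlation. Of 16 B cell and plasma cell genes 1 fell, also adjusted over the list alone, the complement receptor gene Cr2, with a mean of -0.42 ± 0.20 (adjusted p = 0.000126, and adjusted p = 0.483 with an estimated correlation). The call of Cr2 (-0.65 ± 0.18, adjusted p = 0.0344) ended without any one of HFD_CR mice 1, 4 and 5 and LFD mice 1 and 5 (at most -0.53, adjusted p of up to 0.1). By fry, which asks whether the members move one way, the interferon list had adjusted p = 0.0966 and the B cell list adjusted p = 0.134.

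The calls of complement, cell cycle and skeletal muscle in HFD_CR against LFD each ended under several alternatives. Of 16 complement genes 5 rose and 1 fell, 6 and 1 adjusted over the list alone, with C5ar1 at 0.65 ± 0.12. The complement list had adjusted p = 0.0358, and adjusted p = 0.483 with an estimated correlation. That call ended without HFD_CR mouse 1 (adjusted p = 0.141), HFD_CR mouse 3 (adjusted p = 0.0659), LFD mouse 3 (adjusted p = 0.0915) or LFD mouse 5 (adjusted p = 0.0513), with means of 0.10 to 0.14 against 0.14, and in all in 9 of 30 alternatives (0.0982 to 0.14, adjusted p of up to 0.365), so it lay near the threshold. Of 25 cell cycle genes 1 rose, also adjusted over the list alone, Cdk1 (0.97 ± 0.08), with a mean of 0.13 ± 0.07 (adjusted p = 0.0279, and adjusted p = 0.718 with an estimated correlation). The cell cycle mean was 0.08 without HFD_CR mouse 1 (adjusted p = 0.259) and 0.10 without LFD mouse 3 (adjusted p = 0.0933), and in all 7 of 30 alternatives ended the call (0.08 to 0.16, adjusted p of 0.0797 to 0.259). None of 18 skeletal muscle genes passed, with a mean of -0.56 ± 0.65 (adjusted p = 0.0202, and adjusted p = 0.718 with an estimated correlation). The muscle mean was -0.15 without LFD mouse 2 (adjusted p = 0.389), -0.37 without LFD mouse 3 (adjusted p = 0.0959), -0.46 without HFD_CR mouse 1 (adjusted p = 0.0609), -0.46 without HFD_CR mouse 4 (adjusted p = 0.0554) and -0.96 without HFD_CR mouse 2 (adjusted p = 3.57e-05). In all 8 of 29 alternatives ended the muscle call, among them leaving out the 4 arrays with other tissue (-0.21, adjusted p = 0.0632).

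Other lists with no call between HFD_CR and LFD passed under some of 30 or 29 alternatives. They were triglyceride synthesis and lipid uptake (11, -0.14 to -0.0949), NK cells (11, -0.15 to -0.12), mesothelium (7, 0.25 to 0.37), T cells (6, -0.20 to -0.12), the unfolded protein response (3, -0.0529 to -0.0451) and MHC class II presentation (2, -0.18 to -0.14). Immediate early genes (0.14) and smooth muscle (0.24) passed without the 4 arrays with other tissue, and gland epithelium (-0.43) with the mouse number as a block. Single arrays that brought a call when left out were HFD_CR mice 3 and 5 and LFD mice 2, 3 and 5 for triglyceride synthesis, HFD_CR mice 2 and 5, HFD mouse 4 and LFD mice 2, 3, 4 and 6 for NK cells, HFD_CR mice 4 and 5 and LFD mice 3 and 6 for mesothelium, LFD mice 4 and 6 for T cells, HFD_CR mouse 1 and LFD mice 4 and 6 for the unfolded protein response, and LFD mouse 6 for MHC class II presentation.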

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

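The tests of lipogenesis against adipocyte identity and of the clock arms were chosen only after the result was seen. In 156 sets of values (40 lists and 12 genes in each group) 16 values of single mice stood far from the rest of their group, where chance gives about 1 in 20 sets, or 7.8. They came from 9 mice, with 6 from LFD mouse 3, so they are not separate events. Each value here is the distance in log2 from the mean of the group's other mice. LFD mouse 3 stood apart for gland epithelium (2.03), urothelium (0.97), the unfolded protein response (0.27), adipokines (-0.38), endothelium (-0.35) and the cell cycle (-0.21). Skeletal muscle stood apart in HFD_CR mouse 2 (2.00) and HFD mouse 6 (0.94), and gland epithelium in HFD mouse 3 (1.12). B and plasma cell genes were lower in LFD mouse 6 (-0.88), cholesterol biosynthesis in LFD mouse 2 (-0.50), endothelium in HFD mouse 1 (-0.52) and the unfolded protein response in HFD mouse 5 (-0.0918). MHC class II presentation was higher in HFD mouse 3 (0.21), Il6 in HFD mouse 1 (0.23), and Fasn was lower in HFD mouse 4 (-0.11).

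Among 10272 probe sets with no or several gene symbols, which no comparison of genes used, 1860 passed between HFD and LFD, 1066 between HFD_CR and HFD, and 308 between HFD_CR and LFD. Of these 610, 695 and 169 were higher (32.8%, 65.2% and 54.9%), against 59.4%, 40.5% and 63.9% of the changed genes with a symbol, and the difference in balance was not tested. No control samples set a level for these signals.

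The number of changed genes was compared with that in 100 splits of the arrays of each comparison, the real one included. In each comparison 1 of the 100 splits, the real one, gave as many genes. That share is under the bound of 0.05 set beforehand and argues against chance, though with a small margin for HFD_CR against LFD. Not every split was drawn, so others may give as many. The real counts were 6165, 4213 and 2015 for HFD against LFD, HFD_CR against HFD and HFD_CR against LFD, and the highest of the other splits gave 2990, 3275 and 1947.

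De novo lipogenesis genes were lower in HFD and in HFD_CR than in LFD. A lower share of adipocyte RNA alone would lower the adipocyte identity list as much. The lipogenesis list fell further by -0.6474 ± 0.136 in HFD minus LFD (exact permutation p = 0.00216, the smallest 6 mice against 6 can give). In HFD_CR minus LFD, which bears on adipocyte loss that restriction did not undo, the same difference was -0.8216 ± 0.137 (exact permutation p = 0.00433). The means of both lists had been seen before these tests were chosen, so the p values restate the gap. Its size argues against either explanation as the whole source, as far as the identity list gauges the adipocyte share. Muscle and gland RNA in LFD mice 2 and 3 is argued against as the whole source, since without the 4 arrays with other tissue the lipogenesis means were -0.95 in HFD minus LFD and -0.88 in HFD_CR minus LFD. Without LFD mice 3 and 6, which stood high for thermogenic adipocyte genes and for lipogenesis alike, they were -0.76 and -0.68, so a larger share of thermogenic adipocytes in those mice may account for part of the difference. A response to dietary fat, which both high-fat groups shared, stays open as a candidate explanation that the design gives no way to separate from other differences between the diets.

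Clock genes differed between HFD_CR and HFD in opposite directions. The Dbp and Per arm (9 of 9 genes rose) minus the Bmal1 arm (4 of 5 fell) differed by 1.5003 ± 0.211 (exact permutation p = 0.00216, the smallest 5 mice against 6 can give), against 0.03 in HFD minus LFD (exact permutation p = 0.777). All 14 genes of the arms are in the fixed lists and their directions had been seen, so this restates the pattern and does not decide whether the clock phase was shifted. A list of 14 fasting-responsive genes, 9 of them also in the fixed lists, was higher in HFD_CR than in HFD by 0.3312 ± 0.0827 (exact permutation p = 0.00216), with 8 genes higher and 2 lower, which is what a longer time without food at harvest would give. The list was made after the data were seen, so for the 9 shared genes this p value may restate values already known. The 5 fasting-responsive genes outside the fixed lists differed by 0.2905 ± 0.0686 (exact permutation p = 0.00216), with 3 higher and 1 lower, a test added after the others that fell short of the bound set for the whole list. Zbtb16 (1.02) carried much of that mean, and the other members ran from -0.24 (Sesn1) to 0.30 (Ucp3). Neither the hour of harvest nor the last meal is given in the sources used here. The restricted intake itself, a shifted clock, a different hour of harvest and a different time since feeding may each account for the values. The design gives no way to separate them.

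Sly, Astx5, Vmn1r94, Vmn1r103 and Vmn1r129 were lower in HFD than in LFD, with a median of -1.48. They were higher in HFD_CR than in HFD, with a median of 1.26. In HFD_CR minus LFD they ran from -0.37 (Astx5) to -0.04 (Vmn1r129) and none passed, so the signal was low in HFD alone. RNA of male germ cells in the LFD samples is argued against by the median of 14 male germ cell genes, 0.054, none of which fell. Genomic DNA or other multi-copy sequence could lower such genes together, and 9 other genes with symbols of multi-copy sex chromosome families had a median of -0.0412 (quartiles -0.1562 and 0.0048). That lies above the bound of -0.1 set beforehand, as does the median of -0.0823 without the single-copy genes Slx4 and Slx4ip, but by less than the spread of the genes, a condition added after the values were seen. Of these genes only Srsy passed, and it fell by 1.21 (adjusted p = 6.25e-05). Other receptor gene families were slightly lower in HFD. The median was -0.079 for 174 other Vmn1r genes (34 lower, exact permutation p of the set mean 0.00216), -0.0846 for 112 Vmn2r genes (18 lower, exact permutation p = 0.00216) and -0.0914 for 1105 Olfr genes (190 lower, exact permutation p = 0.00866). It was -0.0238 for the 9100 genes with a mean below every array median (exact permutation p = 0.37). Multi-copy sequence or background signal therefore stays open, and no biological explanation was tested.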

How the results depend on the processing

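Leaving out the 4 arrays with other tissue, leaving out LFD mice 3 and 6, and the skeletal muscle covariate were chosen only after the data were seen. Over the named genes, 13459 values under alternatives were compared with the reported ones: 12900 kept their side of the threshold, 523 lost the call, 36 gained one and 0 reversed. A reversal was counted only where the sign changed and at least 1 of the fits compared had a call. Sign changes between values with no call therefore count as kept. Over the lists with preset camera, 3675 were compared in the same way: 3520 kept their side of the threshold, 58 lost the call, 96 gained one and 1 reversed. That was skeletal muscle in HFD minus LFD, from -0.77 to 0.0278 without the 4 arrays with other tissue, by construction, since LFD mice 2 and 3 were left out. Of 405 calls of named genes, counted per gene and comparison, 348 were kept whichever array was left out and 57 were lost in some fits.

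With 1 array left out, 3309 to 3939 genes were higher and 2087 to 2536 lower in HFD minus LFD (18 to 23 lists), 1297 to 1901 and 2000 to 2836 in HFD_CR minus HFD (19 to 20 lists), and 977 to 1440 and 521 to 915 in HFD_CR minus LFD (14 to 21 lists), and 2561 to 3390 genes changed back. Counts fell by construction when at least a 1.5-fold change was required: 830 higher and 302 lower, 190 and 504, 206 and 98, and 545 changed back. With adjusted p under 0.01 there were 1541 lower in HFD minus LFD, 965 higher and 1610 lower in HFD_CR minus HFD, 615 and 352 in HFD_CR minus LFD, and 1942 changed back. Every probe set tested on its own gave 3805 lower in HFD minus LFD, from more tests. Array weights gave 2630 higher in HFD_CR minus HFD, and the cause was not tested. Camera with an estimated correlation called 0, 0 and 0 lists, at smallest adjusted p of 0.0916, 0.108 and 0.158. Splits of the HFD arrays into sets of 3 gave a minimum of 1565 and a median of 1931 genes changed back, from fewer samples.

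The mouse numbers were not used to pair the arrays. Of 16 pairs of the same number 5 had a residual correlation over 0.1 (-0.108 to 0.409, median 0.0415), and 6 of 17 arrays correlated best with an array of their own number. The highest correlation was that of HFD mouse 3 with LFD mouse 3, both high for gland epithelium (1.09 and 2.05 above the median array). Next among the pairs came HFD_CR mouse 2 with LFD mouse 2 (0.303), both high for skeletal muscle (1.95 and 2.97). Whether other tissue in these samples gave the correlations was not tested. How many such matches chance would give was not worked out, so a link by number is not excluded. With the number as a block, 3620 genes were higher and 2436 lower, 1616 and 2394, and 1144 and 629, with 3042 changed back. Signal near background limits what a dim gene can show, and Lep and Scd1, near the upper end of the range, may show less than their full difference. With quantile normalization again Scd1 differed by only -0.04 in HFD minus LFD, so its small difference depends on the normalization. That value is no sign of a larger hidden difference.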

Other observations

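The test of imprinted genes was chosen after Peg3, Mest and Plagl1 had been seen, and its bounds were set before its value was seen, whereas the test without Zim1 was added after. Imprinted genes were among those with large differences: Peg3 was higher than in LFD by 1.47 in HFD and 2.01 in HFD_CR, Zim1 by 0.95 and 1.25, and Mest by 1.61 and 1.49. A hypothesis is that an imprinted growth network may change as a set. Over the 20 measured genes of that list the mean difference was 0.24 in HFD minus LFD (exact permutation p = 0.00433), with 7 genes higher and 3 lower, but the median was 0.0124, so a few members carried the mean. Without Peg3, Mest and Plagl1 the mean was 0.1492 ± 0.0476 (exact permutation p = 0.00433) and the median 0.0083, and without Zim1 as well they were 0.0992 ± 0.0512 (exact permutation p = 0.0714) and 0.0026. Both means lay between the bounds set and left the hypothesis undecided.

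HFD_CR mouse 1 had a mean of 9.48 over the male germ cell list, against 6.69 to 7.72 in the other mice. In it Prm1 measured 11.6 against at most 9.66 in any other mouse, Smcp 10.3 against 7.51, Tnp2 9.92 against 7.33 and Odf1 13.4 against 13.5. On principal components, the first held 39.4% and the second 16.3% of the variance, and LFD mouse 3 lay at 41.2 on the second, against at most 14.8 in the other mice.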
